A study of Arabidopsis thaliana with 28 samples.

How the data were processed

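Roots of Arabidopsis thaliana seedlings (ecotype given as col2, grown on vertical agar plates) were harvested after 0.5, 2 or 48 h in darkness under a stream of air with 1%, 4%, 8% or 21% oxygen. RNA of each sample was labelled with biotin and hybridized to 1 array, giving 28 arrays in 12 groups of 2 or 3, each array with a replicate letter from A to G. The treatment text of 1 array at 8% (48 h, letter B) also carries the word control, and the array was kept at 8% by its title and stated oxygen level. The deposited values are MAS5 probe set signals, a linear intensity per probe set, and the authors scaled each array so that the mean of its signals, trimmed by 2% at each end, was 100. The version of MAS5 and the detection calls were not given. The scaling was kept, and the analysis used log2(signal + 6), where 6 is the 20th percentile of all values rounded to a whole number. The number of arrays per group limits the precision of each value.

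Of the 22810 probe sets, 64 control probe sets were left out. The annotation named 1 gene for 13513 probe sets, several for 503 and none for 8730, and names were taken from it and from RefSeq alone. The 13513 probe sets with 1 gene were tested and counted as 13356 genes, the brightest probe set standing for each of the 146 genes with more than 1. The 503 and 8730 were tested in a second fit of all 22746 probe sets that were not controls, adjusted over all of them. They are given as counts, with values for 4 of them.

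Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 28 arrays (16 residual degrees of freedom), empirical Bayes with an intensity trend, and two-sided tests. Adjusted p values are Benjamini-Hochberg values over the 13513 probe sets of each comparison, with a threshold of 0.05. There were 18 comparisons. In 9 a lowered oxygen level was compared with normal air of the same duration, in 3 oxygen at 1% with 8%, in 4 the response was compared between durations as an interaction, and in 2 durations were compared in normal air. SE is that of the model, SD that of the signals. Folds come from the log2 values with the pseudocount, so folds of dim genes are smaller than the ratio of their signals.

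The replicate letter was checked as a pairing before the fits were compared, by the correlation of arrays with the same letter after removing group means. All 6 pairs at 0.5 h (0.453 to 0.718) and all 12 at 48 h (0.33 to 0.728) were above 0.1, and at 2 h 5 of 8 were (-0.122 to 0.692). The 3 that were not all held the 1% array F. Once group means are removed, the arrays of a group of 2 mirror each other. The pairs are therefore not independent, and the 3 low values cannot be laid on array F and not on array E. Pairs of different letters had medians of -0.2345, -0.0895 and -0.33 at 0.5, 2 and 48 h, but reached 0.667 (4% D with 8% C at 2 h). The letter was therefore taken to pair arrays at 0.5 and 48 h and not all arrays at 2 h, and results with the letter as a block (10 residual degrees of freedom) are given beside those of 0.5 and 48 h, and beside the gene counts of the other comparisons, where they change a call or move a count by over 1.5 times.

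Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes, unless stated otherwise. Of 21 lists, 11 had at least 3 named members and were tested with camera (preset correlation 0.01), adjusted over the 99 tests against normal air, with an estimated correlation as an alternative. Too thin to test were the lists of ethylene synthesis and signalling (1 named member), the group VII ERF and N-degron pathway (1), redox and reactive oxygen (2), early stress signalling (2), root hairs (2), leaf photosynthesis (2), the circadian clock (1), nitrate, ammonium and amino acid metabolism (0), aquaporins (0), and endodermis and suberin (0). Because so few members were named, 9 wider lists were added after the data were seen and tested as a family of 81. Named genes were those with the largest changes that passed the threshold with all arrays of a group beyond all arrays of the other, up to 12 per direction against normal air and up to 5 elsewhere, where interactions had no such condition on arrays. To these were added 11 low-oxygen marker genes, of which 1 had a named probe set of its own, and up to 4 members of each list with the smallest adjusted p. None of the 37 genes named by the order of change had more than 1 probe set.

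Alternatives were quantile normalization, centring each array on its median, pseudocounts of 1.5 and 24, leaving out the dimmest 40% of probe sets, no intensity trend, a fit of the durations compared only, a change of at least 2-fold, the letter as a fixed or a random block, camera with an estimated correlation, fry, and each array left out in turn. A block within each duration and leaving out the arrays of letter C were added after seeing the data. Where leaving out an array left 1 in its group, that array was assumed to vary like those of the other groups.

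The fit was tested on simulated data with 100 genes each changed 4-fold and 16-fold in 4 comparisons. It recovered 86% to 94% of the 4-fold and 99% to 100% of the 16-fold changes, with 6 to 15 wrong calls among 13513 probe sets. The simulated noise had the spread of the fit, was independent between arrays and held no effect of the replicate letter. These rates therefore check the computation and do not give the error rates on the real arrays. No columns were identical, and arrays of the same group correlated at 0.923 to 0.985. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.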

Results

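The series compared roots of Arabidopsis seedlings kept in darkness under 1%, 4% or 8% oxygen with roots kept in normal air (21%) for the same 0.5, 2 or 48 h. The 28 arrays formed 12 groups of 2 or 3 arrays. Each comparison addressed which transcripts differ between a lowered oxygen level and normal air of the same duration. Every gene named as higher or lower at a lowered oxygen level had all its low-oxygen arrays beyond all the control arrays of that duration. Genes are given by symbol, or by locus where the annotation holds no symbol, and positions are those of the TAIR10.1 assembly.

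After 0.5 h, 7 genes rose at 1% oxygen and 6 at 4%, and all 6 of the latter were among the 7. AT4G10270 (chromosome 4, 6374734 to 6375210) had a signal of 844.7 ± 275 (SD, n = 2) at 1% and 857.5 ± 226 (SD, n = 2) at 4%, against 18.4 ± 15.2 (SD, n = 3) in normal air. Its log2 fold changes were 5.32 ± 0.737 (SE, adjusted p = 0.00237) and 5.35 ± 0.737 (SE, adjusted p = 0.00226). AT3G10040, which the annotation also lists as HRA1, a transcription factor gene of the low-oxygen response, rose 34.9-fold at 1% and 30.1-fold at 4%. The others that rose at both levels were AT4G24110, AT4G33560, AT3G27220 and AT5G44730, and AT3G23170 rose at 1% with a log2 fold change of 2.54 ± 0.358 (SE). At 8% oxygen 2 genes rose. These were AT3G27220, at 180.0 ± 4.67 (SD, n = 2) against 22.9 ± 2.50 (SD, n = 3), and the dim AT1G21060, at 11.2 ± 1.02 (SD, n = 2) against 1.75 ± 0.535 (SD, n = 3). No gene passed as lower at this duration by limma, and 234, 190 and 74 genes had an unadjusted p under 0.05 at 1%, 4% and 8% in either direction. With the replicate letter as a block, 3 genes passed at 1% (AT3G27220, AT3G23170 and AT5G44730), 1 at 4% (AT5G44730) and 2 at 8%. AT3G27220 passed at 1% with any single array left out. Without the 1% array of letter D 1 gene passed at 1%, and without the 4% array of letter D 0 passed at 4%; at 8%, 0 passed without either low-oxygen array (C or G) and 1 without any one of the control arrays C, F and G.

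After 2 h, 46 genes were higher at 1% oxygen, 17 at 4% and 3 at 8%. AT5G10040 (chromosome 5, 3143723 to 3144157) had a signal of 1787 ± 27.8 (SD, n = 2) at 1% and 706.6 ± 36.3 (SD, n = 2) at 4%, against 7.33 ± 1.62 (SD, n = 3) in normal air. Its log2 fold changes were 7.08 ± 0.765 (SE, adjusted p = 2.23e-05) and 5.75 ± 0.765 (SE, adjusted p = 0.000687). AT2G17850 rose 58.9-fold at 1% and 27.0-fold at 4%, and AT4G33560 rose 55.6-fold, 32.8-fold and 10.7-fold at 1%, 4% and 8%. CML38, which encodes a calmodulin-like protein, rose from 22.1 ± 10.8 (SD, n = 3) to 725.5 ± 57.2 (SD, n = 2) at 1% and to 296.7 ± 19.2 (SD, n = 2) at 4%. ARL, an ARGOS-like gene of organ growth, rose at 1% with a log2 fold change of 3.92 ± 0.739 (SE, adjusted p = 0.0127). AT4G24110, AT4G10270, AT3G23170, AT5G44730 and AT1G33055 were also among the 12 with the largest changes at 1%, with log2 fold changes from 3.56 to 5.67. At 8% the other genes that rose were AT3G27220, by a log2 fold change of 2.34 ± 0.363 (SE), and AT4G27450, by 1.99 ± 0.314 (SE). No gene passed as lower by limma, and 476, 149 and 92 genes had an unadjusted p under 0.05 at 1%, 4% and 8% in either direction. The replicate letter did not pair all arrays at 2 h, and with it as a block 145 genes were higher and 79 lower at 1%, among them all 46, and 27 were higher and 1 lower at 4%, among them all 17. At 8% the block gave 2 genes, none of them among the 3 above (adjusted p = 0.403 for AT4G33560 and 0.36 each for AT3G27220 and AT4G27450). Of the 12 genes with the largest changes at 1%, 10 passed with any single array left out. The call of ARL was lost without the 1% array E or F or the control array E or F (adjusted p = 0.115, 0.274, 0.0939 and 0.0765), and that of AT1G33055 without the 1% array E or F (adjusted p = 0.0857 and 0.129). At 4%, 7 genes passed without the low-oxygen array of letter D and 10 without that of letter F, and of the 12 with the largest changes AT5G10040, AT4G33560, AT3G27220, AT5G44730 and AT4G27450 passed with any single array left out. At 8%, 0 passed without any one of the 5 arrays, which were C and F at 8% and D, E and F in normal air.

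After 48 h, 10 genes were higher and 3 lower at 1% oxygen, 5 were higher at 4%, and 0 passed at 8%. ICL (AT3G21720, chromosome 3, 7652487 to 7656053), which encodes isocitrate lyase of the glyoxylate cycle, had a signal of 348.1 ± 133 (SD, n = 2) at 1% against 3.53 ± 3.79 (SD, n = 3), a log2 fold change of 5.23 ± 1.01 (SE, adjusted p = 0.0498). AT3G03270, a member of the universal stress protein family, rose 10.7-fold at 1% and 6.50-fold at 4%, from 193.2 ± 57.5 (SD, n = 3) to 2246 ± 1220 (SD, n = 2) and 1266 ± 234 (SD, n = 2). LCR67, which encodes a small defensin-like protein, rose at 1% and 4% by log2 fold changes of 1.96 ± 0.204 (SE) and 1.88 ± 0.204 (SE), from a signal of 0.372 ± 0.182 (SD, n = 3) that lies under the pseudocount. OTC, ornithine carbamoyltransferase of arginine synthesis, rose 1.77-fold at 1%, from 251.6 ± 31.4 (SD, n = 3) to 449.7 ± 46.3 (SD, n = 2). AT4G33560, AT4G10270 and AT3G27220 rose at both levels, and AT3G29970, AT5G10040 and AT4G27450 rose at 1%. The 3 lower genes at 1% were AT2G43590, AT4G36640 and ATG8H, a gene of the ATG8 family of autophagy. AT2G43590 fell from 1951 ± 618 (SD, n = 3) to 401.1 ± 222 (SD, n = 2), with a log2 fold change of -2.33 ± 0.301 (SE, adjusted p = 0.000851). ATG8H fell from 236.8 ± 10.6 (SD, n = 3) to 120.7 ± 7.59 (SD, n = 2), with a log2 fold change of -0.94 ± 0.181 (SE, adjusted p = 0.0498).

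The median log2 fold change of all genes at 1% after 48 h was -0.11, and it was -0.00336 after quantile normalization and 0.06 after centring each array on its median. Against that shift the genes named above kept their directions, which their choice by large changes made likely in advance. With the replicate letter as a block, 108 genes were higher and 197 lower at 1% and 19 higher and 3 lower at 4%, and these included all 13 and all 5 of the genes above. In a fit of the 48 h arrays only, which has fewer arrays, none of these calls held: 0 genes passed by limma at 1% and at 4%, with 266 and 158 at an unadjusted p under 0.05. At 8% the block gave 0 genes as well, limma's smallest adjusted p was 1.0, and 239 genes had an unadjusted p under 0.05. The description of the 8% array B also calls it a control, while its title and its stated oxygen level give 8%; it was kept in the 8% group, and without it 0 genes passed as well. The 1% count was 57 without the 1% array of letter F and 3 without that of letter A, and it was 7, 5 and 6 without the control arrays A, B and F. AT3G03270 and LCR67 passed at 1% with any single array left out. The call of ICL was lost without the control array A, B or F (adjusted p = 0.0908, 0.21 and 0.137 by limma). Its log2 fold change was 5.62 without the 1% array A and 4.84 without the 1% array F. At 4% the count was 56 without the 4% array of letter F, and AT4G33560, AT3G03270 and LCR67 passed with any single array left out.

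**Figure D1:**
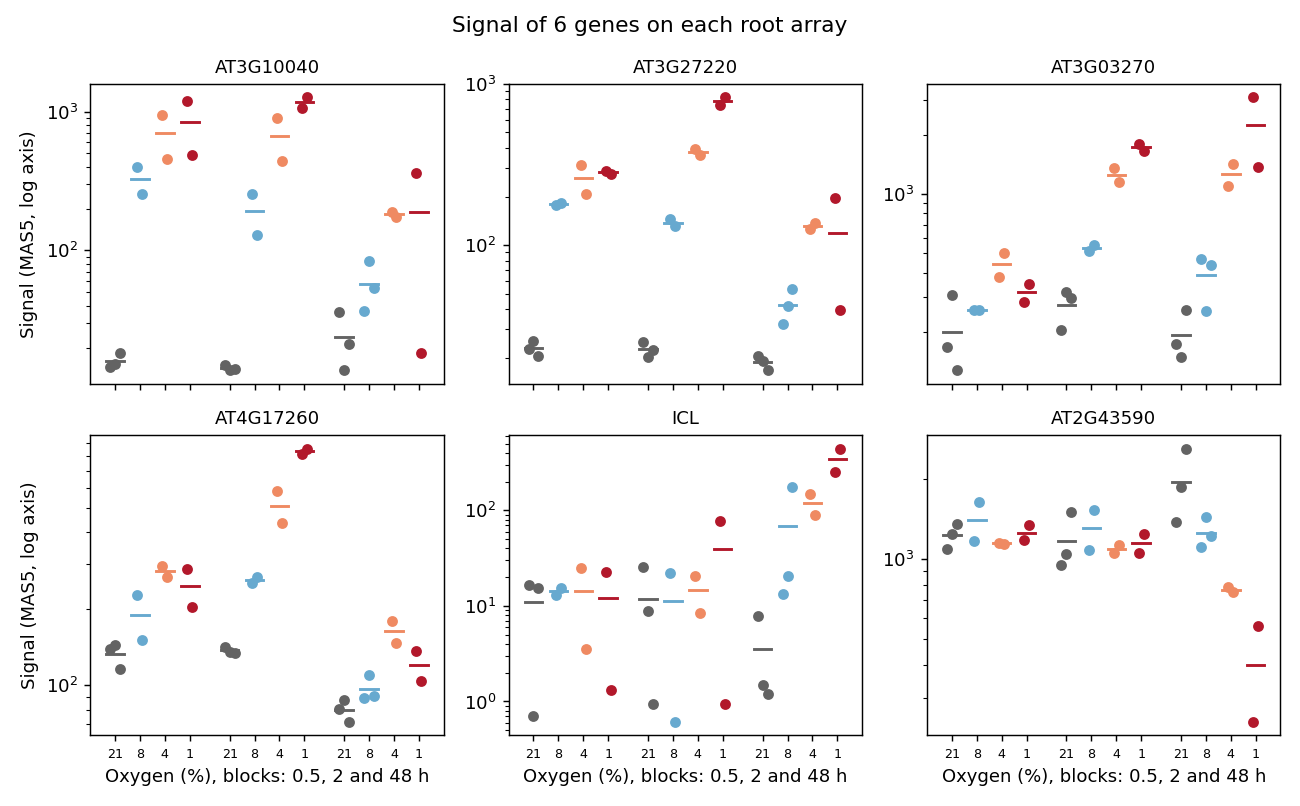
Signals of 6 genes (MAS5 units, log axis) on each of the 28 root arrays, plotted by oxygen level (%) in blocks of 0.5, 2 and 48 h; points are arrays and lines are group means. AT3G10040 lay between 13.7 and 36.0 on the 9 normal-air arrays, and at 1% after 48 h its arrays lay at 361.7 (letter A) and 18.3 (letter F).

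AT3G10040 (HRA1; chromosome 3, 3096345 to 3098417) was the gene among 11 low-oxygen marker genes fixed in advance that had a named probe set of its own. Its signal was 834.5 ± 494, 698.1 ± 349 and 326.8 ± 104 (SD, n = 2 each) at 1%, 4% and 8% after 0.5 h, against 16 ± 2 (SD, n = 3) in normal air. After 2 h it was 1162 ± 148, 665.8 ± 323 and 191.6 ± 87.8 (SD, n = 2 each), against 14.2 ± 0.748 (SD, n = 3). After 48 h it was 190.0 ± 243 (SD, n = 2), 182.2 ± 11.6 (SD, n = 2) and 57.8 ± 23.7 (SD, n = 3), against 23.7 ± 11.3 (SD, n = 3). It passed at 1% and 4% after 0.5 h (adjusted p = 0.00237 and 0.00233) and after 2 h (adjusted p = 8.37e-05 and 0.00123). At 8% its adjusted p was 0.0905 after 0.5 h and 0.388 after 2 h, and after 48 h it was 0.859, 0.507 and 1.0 at 1%, 4% and 8%. With the replicate letter as a block its adjusted p after 0.5 h was 0.0761 at 1% and 0.127 at 4%. Its calls after 0.5 h were lost without the 1% array D (adjusted p = 0.171) and the 4% array D (adjusted p = 0.181), and its call at 4% after 2 h without the 4% array D (adjusted p = 0.105). At 1% after 48 h its log2 fold change was 3.70 without the array F, where it passed (adjusted p = 0.00107), and -0.22 without the array A.

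The list of hypoxia-inducible genes, fixed from prior knowledge, had 23 of its 51 members on named probe sets, and it was higher than other genes in all 9 comparisons with normal air. Its median log2 fold change was 2.00, 1.85 and 0.92 at 1%, 4% and 8% after 0.5 h. After 2 h it was 3.55, 2.52 and 1.43, and after 48 h it was 1.28, 1.59 and 0.62. Single arrays moved the 1% values, to 1.22 without the array D of 0.5 h, and to 0.73 and 2.58 without the arrays A and F of 48 h. Above 0 were 23, 23 and 21 members after 0.5 h, 23, 23 and 22 after 2 h, and 22, 22 and 20 after 48 h. The members that rose over all genes tested numbered 7, 6 and 1 after 0.5 h, 17, 13 and 3 after 2 h, and 6, 4 and 0 after 48 h. Adjusted over the list alone, 14, 17 and 8 members rose after 0.5 h, 21, 20 and 12 after 2 h, and 13, 14 and 4 after 48 h. The camera test gave adjusted p values between 9.55e-125 and 4.58e-09. With an estimated correlation the call held in 8 of these comparisons, and at 8% after 48 h it was lost (adjusted p = 0.148 with an estimated correlation).

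**Figure D2:**
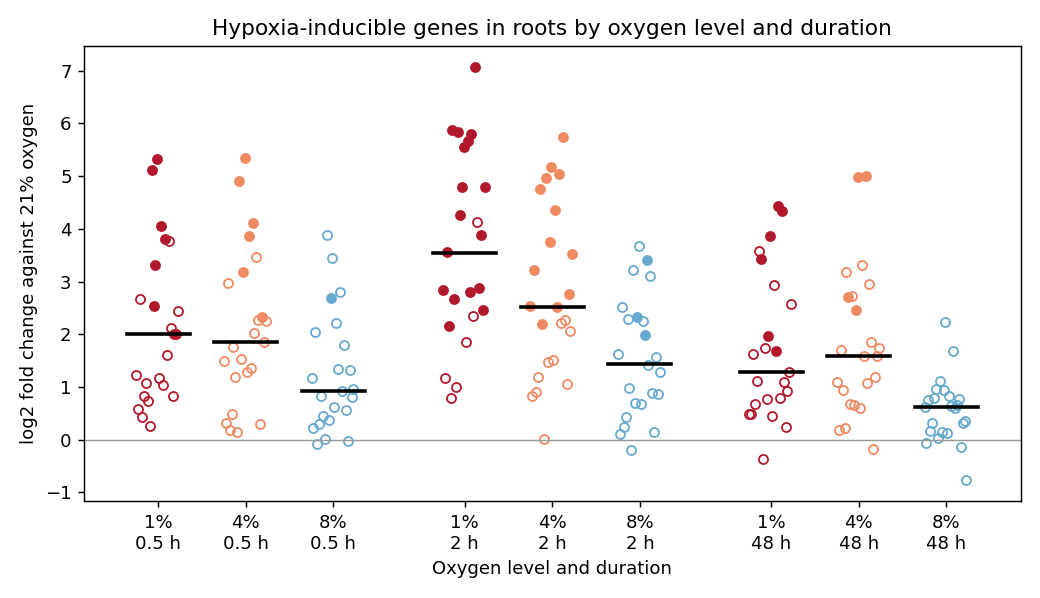
Log2 fold change against normal air of the same duration for the 23 measured hypoxia-inducible genes, by oxygen level (%) and duration (h); each circle is a gene, filled where its adjusted p over all genes was under 0.05, and black lines are list medians. The medians ran from 0.62 at 8% after 48 h to 3.55 at 1% after 2 h.

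The lowest and the mildest oxygen decrease were compared directly. After 2 h, 15 genes were higher at 1% than at 8% oxygen. AT4G30380 had a signal of 66.5 ± 10.7 (SD, n = 2) at 1% against 0.722 ± 0.0701 (SD, n = 2) at 8%, a log2 fold change of 3.42 ± 0.185 (SE, adjusted p = 6.61e-10), with the lower group under the pseudocount. AT3G23170 was 11.8-fold higher, at 444.0 ± 86.4 (SD, n = 2) against 32.6 ± 10.5 (SD, n = 2), and CML38, AT5G42200 and AT3G27220 were 11.4-fold, 6.68-fold and 5.48-fold higher. After 48 h 2 genes were higher at 1% than at 8%, AT3G03270 by 5.47-fold and LCR67 by 3.14-fold. The hypoxia-inducible list was higher at 1% than at 8% by a median log2 of 1.91 after 2 h (adjusted p = 0.000743 with an estimated correlation) and of 0.80 after 48 h (adjusted p = 0.0113 with an estimated correlation). The value of 48 h rested on single arrays, since it was 0.07 without the 1% array A and 1.94 without the 1% array F. After 0.5 h the list's median was 0.68 and its call was lost (adjusted p = 0.105 with an estimated correlation), and it was 1.09, 1.12 and 0.38 without the 1% array F and the 8% arrays C and G. No gene passed between 1% and 8% after 0.5 h by limma, where 249 genes had an unadjusted p under 0.05, and 1 passed without the 1% array F or the 8% array C. After 2 h the count was 6 without the 1% array E, and 5 and 9 without the 8% arrays C and F, and AT3G23170 and AT4G30380 passed with any single array left out. With the replicate letter as a block, 49 genes passed after 2 h, among them 13 of the 15, and the call of CML38 was lost (adjusted p = 0.138). After 48 h it was 43 and 1 without the 1% arrays F and A, 1 and 4 without the 8% arrays B and F, and 62 with the replicate letter as a block. LCR67 passed with any single array left out, and the call of AT3G03270 was lost without the 1% array A or the 8% array B (adjusted p = 0.204 and 0.0757). A fit of the 48 h arrays only gave 0 by limma there, with 181 genes at an unadjusted p under 0.05.

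Whether the response depended on duration was tested as an interaction. At 1% oxygen, 6 genes had a lower response after 48 h than after 2 h, and LCR67 had a higher one by a log2 of 1.71 ± 0.289 (SE, adjusted p = 0.0232). The 6 included AT3G23170, with a difference of -3.49 ± 0.507 (SE, adjusted p = 0.00368), AT4G30380, with -3.35 ± 0.239 (SE, adjusted p = 1.12e-07), and AT5G44730, with -2.96 ± 0.416 (SE, adjusted p = 0.003). AT3G27220 and AT2G43590 had differences of -2.83 ± 0.513 (SE) and -2.33 ± 0.425 (SE). For AT2G43590 the difference was a fall after 48 h and not the loss of a rise. After 2 h its signals were 1056 and 1244 at 1% and 950.3 to 1504 in normal air. The 6th was the lactate dehydrogenase gene AT4G17260, at -2.01, named here after its value was seen. The response of the hypoxia-inducible list was smaller after 48 h by a median log2 of -1.93 at 1% (adjusted p = 0.0116 with an estimated correlation), a value that was -1.01 without the 48 h 1% array F and -2.89 without the 48 h 1% array A. At 4% and 8% its difference was -0.95 and -1.01, and both calls were lost (adjusted p = 0.1 and 0.058 with an estimated correlation). Between 0.5 and 2 h at 1% the list's response grew by a median log2 of 1.61 (adjusted p = 0.0113 with an estimated correlation). In the same comparison 3 genes had a larger response after 2 h, which were AT4G30380, by a log2 of 3.41 ± 0.239 (SE), AT4G17260, by 1.71 ± 0.280 (SE), and AT1G20270, by 1.69 ± 0.290 (SE). At 4% and 8% no single gene differed between 48 and 2 h by limma, with 156 and 136 genes at an unadjusted p under 0.05.

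When the replicate letter was a block, 63 genes passed between 48 and 2 h at 1%, among them all 7. Between 2 and 0.5 h 9 passed, among them 2 of the 3, and the call of AT1G20270 was lost (adjusted p = 0.0606). The number of genes behind these interactions also moved with single arrays. At 1% between 48 and 2 h, 26 genes passed without the 48 h 1% array A, and 4 passed without any one of the control arrays D and E of 2 h and F of 48 h. AT3G23170, AT4G30380 and AT5G44730 passed with any single array left out. At 4%, 1 gene passed without the 2 h 4% array F, 1 without the 48 h 4% array B and 3 without the 48 h 4% array F. Between 2 and 0.5 h at 1%, 1 gene passed without the 0.5 h 1% array F or any one of the control arrays D, E and F of 2 h and C and F of 0.5 h, and AT4G30380 passed with any single array left out.

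The fermentation list had 3 named members of 10, PDC2, which encodes a pyruvate decarboxylase, the lactate dehydrogenase gene AT4G17260, and ALDH2C4, which encodes an aldehyde dehydrogenase. At 1% oxygen for 2 h PDC2 rose by a log2 of 2.96 ± 0.387 (SE, adjusted p = 0.000197) and AT4G17260 by 2.55 ± 0.198 (SE, adjusted p = 1.27e-07), and ALDH2C4 had 0.33 ± 0.510 (SE). At 4% for 2 h PDC2 rose by 2.15 ± 0.387 (SE, adjusted p = 0.0171) and AT4G17260 by 1.83 ± 0.198 (SE, adjusted p = 5.2e-05), and in the other 7 comparisons with normal air 0 members passed. The list median was 0.84, 1.05 and 0.46 at 1%, 4% and 8% after 0.5 h, 2.55, 1.83 and 0.84 after 2 h, and 0.55, 0.96 and 0.25 after 48 h. It was called higher in 8 of the 9 comparisons, each held with an estimated correlation, and the exception was 8% for 48 h (adjusted p = 0.0644). With fry, which tests the list by itself and not against other genes, the call at 8% for 0.5 h was lost (adjusted p = 0.169). The call was lost at 8% for 0.5 h without the 8% array C (adjusted p = 0.163) and at 1% for 48 h without the 1% array A (adjusted p = 0.136). At 4% for 48 h it was lost without the 4% array F (adjusted p = 0.34) and without the control array B (adjusted p = 0.0734). Conversely, the list passed at 8% for 48 h without the control array F (adjusted p = 0.0458) and without the 8% array B (adjusted p = 0.0334). The fermentation response was lower after 48 h than after 2 h by a median log2 of -1.50 at 1% and -0.86 at 4%, and larger after 2 h than after 0.5 h at 1% by 1.58. These 3 calls held with an estimated correlation (adjusted p = 0.00465, 0.023 and 0.000743), and with fry that at 4% was lost (adjusted p = 0.0516).

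Few other lists moved with oxygen. The heat shock list, with 3 named members, was higher at 1% after 48 h, with a median log2 of 0.82 (adjusted p = 0.00565 with an estimated correlation), although no single member passed. Its members AT5G51440, AT5G48570 and AT1G53540 had log2 fold changes of 1.21 ± 0.580, 0.82 ± 0.320 and 0.71 ± 0.443 (SE). It was higher at 1% than at 8% after 48 h by a median log2 of 1.06 (adjusted p = 0.00908 with an estimated correlation). Its response was larger after 48 h than after 2 h at 1% by 1.18 (adjusted p = 0.0217 with an estimated correlation), a call that was lost with fry (adjusted p = 0.0791). Against normal air its call was lost without the 1% array F of 48 h (adjusted p = 0.223). With the replicate letter as a block it passed at 4% after 48 h as well (adjusted p = 0.0361). The ribosome biogenesis list, with 4 named members, was higher at 1% after 48 h by a median log2 of 0.32 (adjusted p = 0.0342 with an estimated correlation). That call was lost with fry (adjusted p = 0.136) and without either 1% array (adjusted p = 0.076 without A and 0.0521 without F), and with the block the list also passed at 4% (adjusted p = 0.0412). The 12 named cytosolic ribosomal proteins were higher at 4% after 48 h by a median log2 of 0.34, a call that was lost (adjusted p = 0.426 with an estimated correlation). It was also lost without the 4% array F (adjusted p = 0.0838) or the control array A (adjusted p = 0.055), and with the block the list passed at 1% and 8% too (adjusted p = 0.0016 and 0.00427). These ribosomal proteins also passed at 1% after 48 h without the 1% array A, the control array B or the control array F (adjusted p = 5.47e-07, 0.0171 and 0.0367), and at 8% without the 8% array A or the control array F (adjusted p = 0.00282 and 0.0211). After 0.5 h they passed without the 1% array D (adjusted p = 0.00179) and without the 4% array D (adjusted p = 0.0418).

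The list of sugar starvation and dark-induced genes, with 4 named members, was lower at 8% after 0.5 h by a median log2 of -0.38, a call that was lost (adjusted p = 0.309 with an estimated correlation). With the block it was also lost at 8% (adjusted p = 0.128), while the list passed as lower at 1% and 4% (adjusted p = 0.0087 and 0.0014). Without the 8% array G its median was above 0 (adjusted p = 0.754), and without the control array C or F the call was lost as well (adjusted p = 0.225 and 0.129). The lists of sucrose cleavage and hexose phosphorylation (3 named members), glycolysis (14), the TCA cycle (10), alternative respiration and mitochondrial stress (5) and the cell cycle (3) were not called in any comparison with normal air. Their adjusted p values there were 0.0521 or more. With one array left out, the cell cycle list passed as lower at 1% after 48 h without the 1% array F (adjusted p = 0.011). The TCA cycle list passed at 4% after 0.5 h without the 4% array D or the control array C (adjusted p = 0.0285 and 0.0262) and after 2 h without the control array F (adjusted p = 0.046). Glycolysis passed at 1% after 0.5 h without the control array C (adjusted p = 0.0448), and ribosome biogenesis at 8% after 2 h without the 8% array C or the control array F (adjusted p = 0.0162 and 0.0156) and at 4% after 48 h without the 4% array B (adjusted p = 0.0124). Over all 99 tests of fixed lists against normal air, 20 lists were called higher and 1 lower, and 18 of these 21 calls held with an estimated correlation and 16 with fry.

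In normal air, where oxygen did not change, 318 genes were higher and 418 lower after 48 h of darkness than after 2 h. HIS1-3, which encodes a linker histone, rose from 99.5 ± 43.2 (SD, n = 3) to 999.2 ± 304 (SD, n = 3), a log2 fold change of 3.31 ± 0.446 (SE, adjusted p = 0.000312). SWEET11, a sugar transporter gene, rose 9.76-fold, and AT1G30760, AT4G37220 and AT4G07820 rose 8.88-fold, 7.49-fold and 6.58-fold. EXPB3, which encodes an expansin of cell wall loosening, fell from 425.2 ± 119 (SD, n = 3) to 30.4 ± 7.20 (SD, n = 3), a log2 fold change of -3.55 ± 0.477 (SE, adjusted p = 0.000312). AT4G30650, the transcription factor gene BZIP61, AT5G59250 and AT1G23100 fell as well, with log2 fold changes of -2.81, -2.40, -2.36 and -2.36. Of the 10 named TCA cycle genes 5 fell, including AT5G23250 by a log2 of -0.98 ± 0.186 (SE) and SDH1-1, a succinate dehydrogenase subunit gene, by -1.26 ± 0.245 (SE). The TCA cycle list was lower by a median log2 of -0.64 (adjusted p = 0.0113 with an estimated correlation), and the ribosome biogenesis list by -0.68 (adjusted p = 0.0412 with an estimated correlation). The sugar starvation list was higher by a median log2 of 1.24, with ATL8 and IVD risen by 1.86 ± 0.450 (SE) and 1.13 ± 0.305 (SE) among its 4 members, but its call was lost (adjusted p = 0.0935 with an estimated correlation). Glycolysis, the ribosomal proteins and the cell cycle had medians of -0.29, -0.80 and -0.86 and calls that were lost too (adjusted p = 0.179, 0.1 and 0.259 with an estimated correlation).

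The time comparison in normal air set arrays of letters A, B and F against letters D, E and F, so only letter F was present at both times. The count of 736 genes was 358, 365 and 336 without the 2 h arrays D, E and F, and 406 and 488 without the 48 h arrays A and F. With all replicate letters as a block it was 2682, among them 696 of the 736. Of the 10 genes with the largest changes 8 passed with any single array left out; the call of AT4G07820 was lost without the 2 h array D or E or the 48 h array F (adjusted p = 0.054, 0.0808 and 0.0615), and that of BZIP61 without the 2 h array E or F or the 48 h array A or B (adjusted p = 0.17, 0.16, 0.121 and 0.185). The hypoxia-inducible list had a median of 0.26 in this comparison and was not called, but it passed without the 48 h array B (adjusted p = 0.0191) and with the replicate letter as a block. Between 2 and 0.5 h in normal air no gene passed by limma, with 240 genes at an unadjusted p under 0.05.

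The genes that rose overlapped between oxygen levels and durations. All 17 genes higher at 4% for 2 h were among the 46 at 1%, where independent lists of these sizes would share 0.0586, and all 3 at 8%, among them AT4G27450, were among both, where 0.0103 and 0.00382 would be shared. After 0.5 h 6 genes were shared by 1% and 4% (0.00314 for independent lists), and AT3G27220 was the 1 shared by 1% and 8% (0.00105) and by 4% and 8% (0.000898). After 48 h all 5 genes higher at 4% were among the 10 at 1% (0.00374). In 20 simulations with no effect the overlap of genes that passed was 0 in each, but hardly any gene passes there, so this is no reference for lists of these sizes. In the same simulations, in a test chosen after seeing the data, the top-ranked genes of lists as long as those of 1% and 4% shared a mean of 0.5, 1.7 and 0.3 genes after 0.5, 2 and 48 h. Those of 1% and 8% shared 0.25 and 0.35 after 0.5 and 2 h, and those of 4% and 8% 0.1 and 0.25. The 3 control arrays cannot be split into 2 sets of 2 or more, so part of the overlap may come from the shared controls. The simulated arrays also held no effect of the replicate letter, while the groups compared share letters, such as D and F at 1% and 4% after 0.5 h. The simulated means may therefore be too low a reference for these arrays. Between durations, which share no arrays, all 7 genes higher at 1% after 0.5 h were higher after 2 h (0.0241), 6 of those higher after 48 h were higher after 2 h (0.0344), and 3 were higher after 0.5 and 48 h (0.00524). At 4% all 6 genes of 0.5 h were higher after 2 h (0.00764), and 4 of the 5 genes of 48 h were higher after 2 h (0.00636). The durations share the spread estimated for each gene in the 1 fit, and letter F occurs at all of them. Independent lists may therefore be too low a reference here as well. With the replicate letter as a block, the lists of higher genes at 1% and 4% after 0.5 h held 3 and 1 genes and shared 1 (0.000225), 1% and 8% shared 1 (0.000449), and 4% and 8% shared 0. After 48 h the blocked lists of 1% and 4% shared 15 of the 19 genes higher at 4% (0.154), and at 1% 2 of the 3 genes of 0.5 h were higher after 48 h (0.0243).

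The arrays differed by replicate letter as well as by oxygen. The first principal component held 28.4% of the variance. Each taken alone, the letter accounted for 94.3% of its spread, the duration for 48.1% and the oxygen level for 1.73%. These shares overlap, because several letters occur at a single duration. The oxygen level had 1.68% and 2.1% on components 2 and 3. On component 4, with 5.91% of the variance, it had 41.4%, the letter 69.8% and the duration 16.9%. Transcripts of the plastid genome moved with the letter, with a median signal of 151 to 177 on the 3 arrays of letter C and of 16.3 to 68.8 on the other arrays. The signal for 25S rRNA ran from 102.1 to 2246, and the ratio of 3' to 5' signals of GAPDH from 0.702 to 1.76. For actin this ratio ran from 4.44 to 20.1. It was 15.3 to 20.1 for letter C, 4.44 to 6.84 for letter G and 6.07 to 15.5 for letter F. Letter D was present at 1% and 4% after 0.5 h and not in normal air of that duration, where the letters were C, F and G. For its arrays of 0.5 h, oxygen and letter cannot be told apart by a control of the same letter and duration. Letter C was present at 8% after 0.5 and 2 h and in normal air after 0.5 h, and not in normal air after 2 h. Without its 3 arrays, an alternative chosen after seeing the data, 0 genes passed at 8% after 0.5 h and 0 after 2 h, against 2 and 3 with them, and the hypoxia-inducible list kept its call at 8% after both. Within letters, the hypoxia-inducible list had a median log2 difference of 1.05 (C) and 1.08 (G) at 8% after 0.5 h, 3.01 (E) and 3.55 (F) at 1% after 2 h, and 2.46 (A) and 0.40 (F) at 1% after 48 h.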

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

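All tests of explanations in this part were chosen only after the result was seen, while the interactions and the splits of the arrays were planned.

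The response of the hypoxia-inducible list differed between durations by a test of the difference, being smaller after 48 h than after 2 h at 1% oxygen by a median log2 of -1.93. Part of the 1% value rests on array F of 1% after 48 h. The 4% and 8% differences stayed at -0.70 or below with any array left out. They lost their calls with an estimated correlation (adjusted p = 0.1 and 0.058) and with fry (adjusted p = 0.342 and 0.282). That array as the whole cause of the lower medians is argued against, because the 4% and 8% differences, -0.95 and -1.01, do not hold it. Without it the 1% difference was -1.01, a value that rests on the single 1% array A of 48 h. A shift of a replicate letter common to all oxygen levels is argued against only where it is the same at 2 and 48 h. With the letter as a block and without the 1% array F of 48 h, the 1%, 4% and 8% differences were -0.78, -1.07 and -1.09. The largest adjusted p over these 3 was 0.0365 with an estimated correlation. The letter did not pair all arrays at 2 h, so the block may leave part of a letter shift in these differences. They also share the normal-air arrays and are not 3 separate supports. A letter shift that differs between durations therefore stays open. Different responses of the letters stay open too, since the values within letter F, -0.88 at 4% and -0.69 at 8%, rest on single arrays. A higher level of these genes in the 48 h normal-air arrays is argued against as the whole cause, because the list median there was 0.26 above 2 h, less than the smallest of these losses. That median is from the fit without the block, and with the replicate letter as a block the list passed in that comparison. The mean log2 signal of the list was 5.813 to 5.877 on the normal-air arrays of 2 h and 6.278 to 6.424 on those of 48 h. At 4% it was 8.475 and 8.782 after 2 h, and 8.089 and 8.258 after 48 h. At 8% it was 7.302 and 7.478 after 2 h, and 6.548 to 7.14 after 48 h. A rise in normal air therefore stays open as a part of the smaller response. The duration itself, time of day and plant age stay open as untested, and a smaller response to long exposure may be put forward as a hypothesis only.

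On array F of 1% after 48 h, AT3G10040 had a signal of 18.3, and the hypoxia-inducible list lay a median log2 of 0.40 above the normal-air array of the same letter, against 2.46 for letter A. A normal-air array under a wrong label was tested on 2 gene sets. The first, 45 genes outside the list that passed with letter A alone, had a median of 0.13 with 27 in the same direction, which on its own went with a wrong label; the second, chosen after that value was seen, held 22 genes that passed at 4% after 48 h with the block and had a median of 0.96 with 21 in the same direction. The second, against 0.0453 and 0.245 for the same genes on the other normal-air arrays, goes against a normal-air array. Its genes were chosen partly on these same normal-air arrays, so the 0.0453 and 0.245 do not show where a normal-air array outside the choice would lie. The first set was chosen on the array A alone, so its median near 0 on the array F may come from that choice. Besides these 2 sets, the 7 genes that passed at 1% after 0.5 h were chosen at another duration. On this array their median was 1.01 above the normal-air array F, with 6 in the same direction. It was 0.213 and 0.147 on the normal-air arrays A and B. For these 7 genes the values argue against a normal-air array. They rest on 1 array, so the label as a whole is not settled. A GAPDH ratio of 1.03 and an actin ratio of 10.2 argue against degraded RNA, being within the 0.893 to 1.41 and 6.07 to 15.5 of the other 10 letter F arrays. More oxygen at these roots shortly before sampling stays open, because the genes that passed at 0.5 h kept 45.3% of the letter A response, while 2 sets of later genes kept -0.59% (17 genes, chosen on letter A) and 69.9% (8 genes, chosen after the first value was seen); the 8 held AGL86 and SK15, whose letter A responses of 0.02 and -0.01 leave their share without meaning (84.3% without these 2), and a difference between plants of the 2 letters was not tested.

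In the same interaction at 1%, 7 genes differed between 48 and 2 h. Their log2 differences were 1.71 for LCR67, -3.49 for AT3G23170, -3.35 for AT4G30380, -2.96 for AT5G44730, -2.83 for AT3G27220 and -2.33 for AT2G43590, besides AT4G17260. Between 2 and 0.5 h at 1%, 3 genes differed, by 3.41 for AT4G30380, 1.71 for AT4G17260 and 1.69 for AT1G20270. The hypoxia-inducible list differed by 1.61 in that comparison and the fermentation list by 1.58. Between 48 and 2 h the fermentation list differed by -1.50 at 1% and -0.86 at 4%, and the heat shock list by 1.18 at 1%.

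Probe sets that the annotation gives no gene or several genes were in no comparison above, and many of them differed from normal air. They numbered 4, 4 and 1 at 1%, 4% and 8% after 0.5 h, 51, 16 and 2 after 2 h, and 19 and 10 at 1% and 4% after 48 h. At 1% after 2 h, 46 were higher and 5 lower. The 2 with the largest rises went from 11.5 ± 1.89 (SD, n = 3) to 1870 ± 3.80 (SD, n = 2) and from 41.4 ± 5.34 (SD, n = 3) to 1895 ± 353 (SD, n = 2). The 2 with the largest falls changed by a log2 of -1.39 and -1.29.

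Each comparison of 3 arrays with 3 allowed 10 splits of the arrays, too few for a share under 0.05. At 8% after 48 h all 10 splits gave as many genes as the real one, which gave 0, and the highest other gave 18. That split set both arrays of letter A and the 8% array F against both arrays of letter B and the normal-air array F, which points to a structure of the samples by letter. The other 3 splits that, like the real one, part every letter gave 0, and the blocked value was 0. Between 2 and 0.5 h in normal air all 10 splits gave 0. Between 48 and 2 h in normal air 1 split of 10, the real one, gave as many as 736 genes, and the highest other gave 1.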

How the results depend on the processing

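The replicate block within each duration and the omission of letter C were chosen only after the data were seen. Of 18 gene counts, those within 1.5 times of the value reported numbered 17 with a 2-fold change, median centring or the dim filter, 16 without an intensity trend or with quantile normalization, 15 with either pseudocount, 12 with a fit of the durations compared only, 11 without letter C, 7 with the replicate block, 5 with a random block and, of the 16 it could estimate, 6 with the block within durations. The hypoxia-inducible list kept its direction against normal air under all alternatives run. Its medians at 1%, 4% and 8% ranged over 1.22 to 2.14, 1.40 to 2.04 and 0.62 to 1.28 after 0.5 h, 2.76 to 3.79, 2.25 to 2.66 and 1.33 to 1.71 after 2 h, and 0.73 to 2.58, 1.25 to 1.78 and 0.40 to 0.79 after 48 h. Of 86 named gene values 0 changed direction under a scaling alternative. These genes were chosen for large changes that passed, so a change of direction was hardly possible. Among single gene values, 934 were the same, 142 no longer passed and 4 newly passed under these alternatives, and 409, 160 and 3 with single arrays left out. Among lists other than the hypoxia-inducible list, 1012 results were the same, 11 were lost and 30 newly passed, for the hypoxia-inducible list over all 18 comparisons 203 were the same, 9 were lost and 2 newly passed, and of overlaps 234 were the same and 54 moved. For genes and lists, the same includes results that passed neither as reported nor under the alternative. The numbers lost are therefore not shares of all these results. The folds of genes with signals near or under the pseudocount of 6 are limited by it. Where a count moved, the cause was not tested, apart from the fewer arrays or probe sets that an alternative holds.

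With the replicate block, the letter pairs arrays at 0.5 and 48 h. There the counts were 3 at 1% and 1 at 4% after 0.5 h, 305 at 1% and 22 at 4% after 48 h, and 62 for 1% against 8% after 48 h. Where the letter does not pair all arrays, the block gave 224 at 1% (145 higher and 79 lower) and 28 at 4% after 2 h, 2 at 8% after 2 h, none among the 3 reported, 49 for 1% against 8% after 2 h, 63 and 9 for the 1% interactions of 48 with 2 h and of 2 with 0.5 h, and 2682 in normal air between 48 and 2 h. The block within each duration gave 2, 189 (131 higher and 58 lower) and 255 at 1% after 0.5, 2 and 48 h, 0 and 19 at 4% after 0.5 and 48 h, 0 and 1 at 8% after 2 and 48 h, 25 and 59 for 1% against 8% after 2 and 48 h, and 51 for the 1% interaction of 48 with 2 h. It could not estimate the 2 comparisons of durations in normal air, because its letter terms take up the difference between durations. With it the list's adjusted p for 1% against 8% after 0.5 h was 0.225. A random block (correlation 0.632) gave 222 (151 higher and 71 lower) and 240 at 1% after 2 and 48 h, 31 and 34 at 4%, 5 and 5 at 8% after 0.5 and 2 h, 2, 63 and 67 for 1% against 8% after 0.5, 2 and 48 h, 59 and 14 for the 1% interactions of 48 with 2 h and of 2 with 0.5 h, 2 for that of 48 with 2 h at 4%, and 2566 in normal air between 48 and 2 h. It was not run for lists, since camera takes no random block.

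Without letter C the counts were 0 and 0 at 8% after 0.5 and 2 h, 5 at 1% after 48 h, 1 and 6 for 1% against 8% after 0.5 and 2 h, and 4 and 1 for the 1% interactions of 48 with 2 h and of 2 with 0.5 h. A fit of the durations compared only gave 1 and 7 at 8% after 0.5 and 2 h, 0 and 0 at 1% and 4% after 48 h, 0 for 1% against 8% after 48 h, and 458 in normal air between 48 and 2 h; it has fewer arrays. A 2-fold change left 407 of these 736 genes. Quantile normalization gave 1 for 1% against 8% after 0.5 h and 1 for the 1% interaction of 2 with 0.5 h, and median centring 0 at 8% after 2 h. Without an intensity trend the counts were 1 at 8% after 0.5 h and 4 for the 1% interaction of 48 with 2 h, and without the dimmest 40% of probe sets 1 at 8% after 0.5 h. A pseudocount of 1.5 gave 1 at 8% after 0.5 h and 4 and 1 for the 1% interactions of 48 with 2 h and of 2 with 0.5 h, and a pseudocount of 24 gave 0 at 8% after 2 h, 2 for 1% against 8% after 0.5 h and 1 for the interaction of 48 with 2 h at 4%. The hypoxia-inducible list's adjusted p at 8% after 48 h was 0.148 with an estimated correlation and 0.454 with fry, and for 1% against 8% after 0.5 h 0.105 and 0.21.

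With single arrays left out, the counts ranged over 1 to 7, 0 to 7 and 0 to 1 at 1%, 4% and 8% after 0.5 h, 32 to 38, 7 to 16 and 0 to 0 after 2 h, and 3 to 57, 5 to 56 and 0 to 0 after 48 h. They ranged over 0 to 1, 5 to 11 and 1 to 43 for 1% against 8% after 0.5, 2 and 48 h, 4 to 26, 0 to 3 and 0 to 0 for the interactions of 48 with 2 h at 1%, 4% and 8%, and 1 to 4 for that of 2 with 0.5 h. In normal air they ranged over 0 to 0 between 2 and 0.5 h and 336 to 656 between 48 and 2 h. The sugar starvation list reversed at 8% after 0.5 h without the 8% array G, with adjusted p values of 0.000467 to 0.754 over the arrays left out.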

Other observations

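The wider gene lists and the test of carbon starvation in this part were chosen only after the data were seen.

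Because the fixed lists had few named members, 9 wider lists were tested. The 114 named cytosolic ribosomal proteins had a median log2 fold change of 0.23, 0.22 and -0.03 at 1%, 4% and 8% after 0.5 h, -0.05, -0.11 and -0.06 after 2 h, and 0.13, 0.39 and 0.12 after 48 h. The 49 genes of the mitochondrial respiratory chain and ATP synthase had medians of 0.30 and 0.25 at 1% and 4% after 0.5 h and of -0.01 and -0.10 after 2 h. In normal air both lists had lower medians after 48 h than after 2 h, -0.75 for the ribosomal proteins and -0.62 for the respiratory chain. With an estimated correlation their adjusted p values in normal air were 0.42 and 0.507. Of the 81 tests of these lists against normal air 20 were called higher and 8 lower, and 0 held with an estimated correlation.

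The 12 named genes of the wider heat shock list had a median of 0.47 at 1% after 48 h (adjusted p = 0.409 with an estimated correlation). The 49 class III peroxidases, enzymes of the cell wall, had a median of -0.36 at 1% after 48 h (adjusted p = 0.959 with an estimated correlation), and the 8 extensins one of -0.20 (adjusted p = 0.985 with an estimated correlation). The 19 universal stress proteins at 1% after 48 h had a median of -0.00195 and a mean of 0.21 and were called higher, so median and test differed in sign (adjusted p = 0.788 with an estimated correlation), and the median was above 0 after quantile normalization and median centring. The 69 plastid-encoded genes had medians of -0.70 and -0.45 at 1% and 4% after 2 h (adjusted p = 0.959 and 0.959 with an estimated correlation), and their level moved with the replicate letter. The 8 nuclear-encoded photosynthesis genes had a median of 0.56 at 1% after 2 h (adjusted p = 0.959 with an estimated correlation).

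ICL, a gene of the glyoxylate cycle, was higher at 1% after 48 h, a call that was lost without any one of the control arrays. Carbon starvation was tested as a candidate explanation of this rise. The 9 named genes of the wider sugar starvation list had a median of -0.31 in that comparison, with an adjusted p of 0.851, and the 4 of the fixed list had -0.38, with an adjusted p of 0.635. These p values miss the threshold on few genes and do not show that the lists did not differ, so a bound set on the p alone was too weak to exclude the explanation. The fixed list also had a median 1.24 higher after 48 h than after 2 h in normal air, and a starvation common to both oxygen levels would not appear in this comparison. Carbon starvation stays open.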
